A study of Homo sapiens with 4 samples.

How the data were processed

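Polyadenylated RNA of Jurkat cells, an established human T-cell acute lymphoblastic leukaemia line, was sequenced on an Illumina NovaSeq from 2 libraries of cells treated with GNE987 and 2 of untreated cells, per the labels. GNE987 is a degrader that joins a ligand of BET bromodomain proteins to a ligand of the VHL ubiquitin ligase. The labels give the dose as 25 nmol, with no volume, and the time as 24 h. RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols, a kit that does not mark the strand. Reads of a gene and of an overlapping or antisense gene therefore cannot be told apart, and neither can reads of near-identical copies such as histone genes.

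The submitters' processing notes name HISAT2 2.2.0 and the build hg38. The counting tool, the annotation and the strand setting are not given in the sources used here. The deposited table held 26733 genes with several kinds of column. Whole-number counts per gene and library were the authors' raw values, judged from the values and the column names. A normalized signal was deposited beside them, equal to the count divided by 1 size factor per library, and 100% of these values gave back the deposited count within 0.01 when multiplied by it. The authors' size factors were equal to those DESeq2 gives on all genes, from 0.793 to 1.27. The deposited FPKM values were proportional to the normalized signal of the same gene in every library. The authors' deposited table also held a log2 fold change and a p-value with an adjusted p-value per gene, by a test not given in the sources used here. An adjusted p of exactly 1 was listed for 6737 genes in the authors' deposited table. Only the raw counts entered the tests below, and the authors' own comparison is given as a separate description.

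All 26733 gene identifiers matched GENCODE release 29, which supplied the coordinates on GRCh38. Gene names were those of the table, except 20 that a spreadsheet had turned into dates and that were restored from the identifier. The total count was 17024157 and 16041022 in the treated libraries and 18938465 and 18441248 in the untreated ones. At this depth 3 counts in a library equal 0.158 to 0.187 CPM (counts scaled to the library total), which is the floor for a gene without reads and covers counting error only. Reads carry no molecular identifiers.

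Genes were kept with filterByExpr of edgeR 4.0.16 (a minimum count of 10 and a minimum total of 15), which left 15910 genes and removed 10823. Counts were scaled with TMM factors and tested with the quasi-likelihood F test of edgeR (estimateDisp, glmQLFit and glmQLFTest with default settings) in R 4.3.3, treated against untreated, with 2 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was an adjusted p of 0.05. Adjusted p-values of genes are from this test unless another is named. The standard error of a log2 fold change is its size divided by the square root of F. CPM values are TMM-scaled, except in shares of reads, which use the total count. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

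Before the data were examined, 28 gene lists with 673 entries were fixed, of which 25 entries had no row here and were not analysed. They cover BET proteins, elongation factors, T-cell and leukaemia genes, growth, cell cycle, death and stress pathways, controls, and markers of other cell types. Lists were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. With an estimated correlation camera has only the 2 residual degrees of freedom, so few lists can pass and a failure there is weak evidence. The rule for genes named in the text was fixed at the same time. It takes BRD2, BRD3, MYC, HEXIM1, TAL1, LCK, BCL2, CDK6 and CDKN1A in every case, and some items under the rule are not reported here. It adds the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 10 CPM, an ordinary symbol and the same direction in all 4 pairs of a treated and an untreated library. Up to 4 members with the smallest p per pathway list and up to 3 members with the highest mean of the other lists complete it.

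The alternatives were DESeq2 size factors (RLE), upper-quartile scaling, library size alone, no filter on low counts, a filter of 10 CPM in 2 libraries, the Wald test of DESeq2 1.42.0, edgeR with robust estimation, the replicate number as a block, and each library left out in turn. Leaving out a library leaves 1 sample in a group, which is then assumed to vary like the other group. Without a treated library the spread is that of the untreated pair, which differed more than the treated pair. The chi-square per degree of freedom was 36.0 for the untreated pair and 4.76 for the treated pair.

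The scripts were tested on simulated data with known answers: counts for 15910 genes drawn from the untreated means, the library sizes and the gene-wise dispersions, with 200 changed genes. Of 50 genes changed 1.5-fold 0% were recovered, and of 50 changed 2-fold 22%, of 50 changed 4-fold 72% and of 50 changed 8-fold 80%. The test made 14 false calls among 15710 unchanged genes in that draw. Over 8 further draws with 200 changed genes, 10.6% of 781 calls were false, above the nominal share, and this fell to 2.91% of 825 calls with trended dispersions. With 11000 changed genes, a number near that called here, 1.33% of 32890 calls over 4 draws were false. The list test found 10 of 10 lists of 30 raised genes and called 0 of 10 unchanged lists. The simulated genes were drawn independently of each other. In the real data the estimated correlation was 0.235 for the T-cell list and 0.788 for the histone list. False list calls among correlated genes were therefore not tested. Figures were drawn with matplotlib 3.10.9.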

Results

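Gene expression was measured in Jurkat cells, a line derived from T-cell acute lymphoblastic leukaemia, after 24 h with GNE987 at a labelled dose of 25 nmol and in untreated cells. Each group had 2 libraries. Total counts were 17024157 and 16041022 in the treated libraries and 18938465 and 18441248 in the untreated ones. The log2 CPM of the tested genes correlated with r = 0.995 across genes between the treated libraries and with r = 0.981 between the untreated ones; genes are not independent replicates. The counts of the untreated libraries differed by a chi-square of 36.0 per degree of freedom, against 4.76 for the treated pair, so neither pair was a single library deposited again. Untreated replicate 2 lay between untreated replicate 1 and the treated libraries, as the plot of positions by gene class shows, and values without it are given below.

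The first comparison asked which genes changed when the leukaemia cells were exposed to the BET degrader. MYC, a transcription factor that drives growth, fell from 311.6 ± 43.5 to 15.6 ± 0.031 CPM (SD, n = 2), a log2 fold change of -4.32 ± 0.17 (SE). LCK, the kinase that starts T-cell receptor signalling, fell from 866.6 ± 119 to 61.1 ± 1.39 CPM, a change of -3.83 ± 0.17. TAL1, a leukaemia transcription factor, and CDK6, a G1 cyclin-dependent kinase, fell too, with log2 fold changes of -1.77 ± 0.13 and -1.68 ± 0.16. HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose by 2.01 ± 0.37 and CDKN1A, the cell cycle inhibitor p21, by 2.33 ± 0.47. Untreated replicate 1 had 44.9 CPM of HEXIM1 and 18.4 CPM of CDKN1A, and untreated replicate 2 had 97.4 and 51.5 CPM; without untreated replicate 2 the log2 fold changes were 2.72 and 3.31. Adjusted p-values were 0.000292 for MYC and LCK, 0.000426 for TAL1, 0.000838 for CDK6, 0.0056 for HEXIM1 and 0.00783 for CDKN1A (edgeR quasi-likelihood test, Benjamini-Hochberg). BCL2, an inhibitor of apoptosis, had 17.4 ± 0.0545 CPM with GNE987 and 16.7 ± 1.6 without (adjusted p = 0.761). MYC lies on chromosome 8 from 127735434 to 127741434 and LCK on chromosome 1 from 32251239 to 32286165 (GRCh38). CDKN1A did not pass the threshold without GNE987 replicate 1 (adjusted p = 0.0523) or without GNE987 replicate 2 (0.0551).

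BRD2 and BRD3, which encode BET proteins, rose. BRD2 went from 341.04 ± 146 to 1284 ± 65.5 CPM (log2 fold change 1.91 ± 0.31, adjusted p = 0.00391) and BRD3 from 30.3 ± 3.37 to 55.0 ± 2.4 CPM (0.86 ± 0.13, adjusted p = 0.00335). In untreated replicate 1 BRD2 was at 238 CPM and in untreated replicate 2 at 444 CPM. Of 20 tested genes of P-TEFb, its regulators and related transcription machinery 11 rose and 4 fell. NELFA fell by 2.61 ± 0.18 and SUPT5H rose by 1.56 ± 0.23, and the list as a whole did not pass (camera adjusted p = 0.149). With library size alone 7 rose and 4 fell, and the median of 0.37 became 0.0009.

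**Figure D1:**
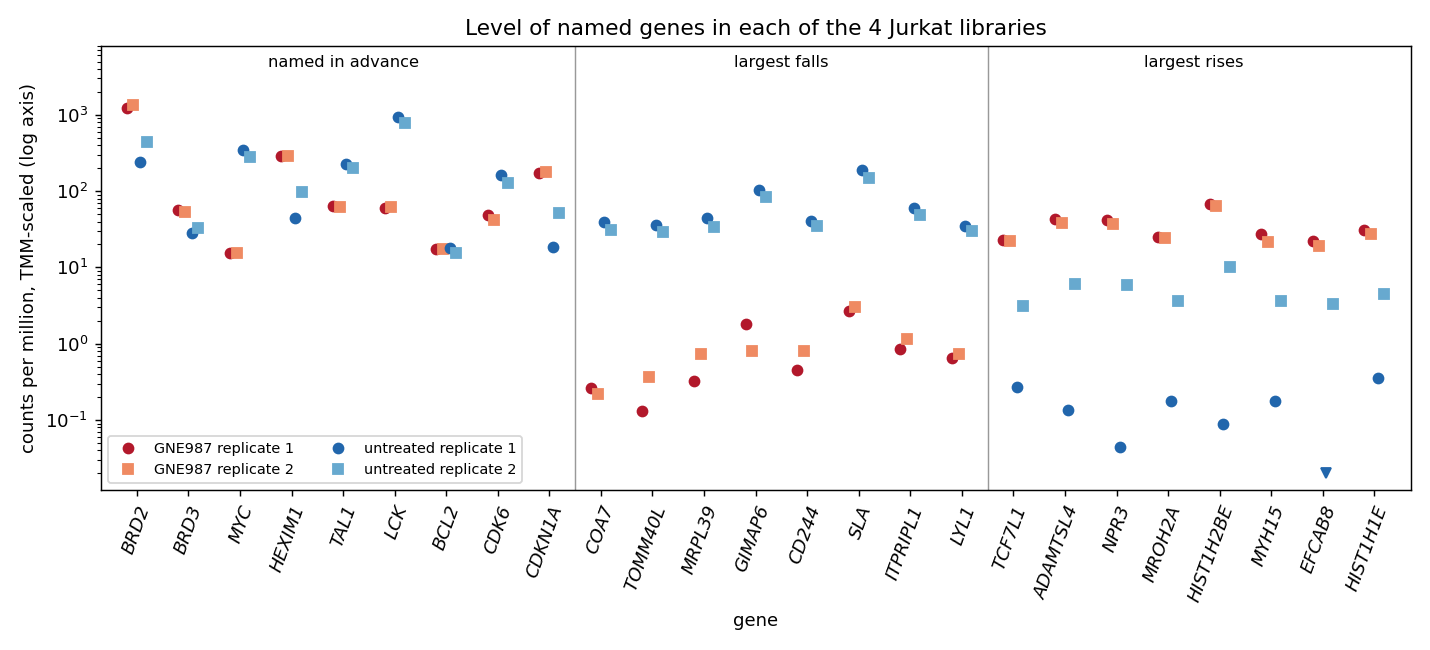
TMM-scaled CPM on a log axis (vertical) of genes named in advance, the 8 largest falls and the 8 largest rises (horizontal), 1 point per library; the downward triangle is a gene without reads in untreated replicate 1. MYC is at 15.6 CPM in both treated libraries and at 342 and 281 CPM in the untreated ones, and for the largest rises untreated replicate 2 lies between untreated replicate 1 and the treated libraries.

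Transcripts of 11387 of 15910 genes changed, 5467 higher and 5920 lower with GNE987. With a change of at least 2-fold the number was 8303, of which 3919 were higher and 4384 lower. The largest falls among genes with a mean of at least 10 CPM were those of COA7, TOMM40L, MRPL39, GIMAP6, CD244, SLA, ITPRIPL1 and LYL1, from -7.16 to -5.54 on the log2 scale (-7.30 to -5.47 without GNE987 replicate 1 and -7.87 to -5.61 without GNE987 replicate 2). COA7, a cytochrome c oxidase assembly factor, went from 35.4 ± 6.43 to 0.24 ± 0.032 CPM, and SLA, an adaptor that dampens T-cell receptor signalling, from 170.0 ± 28.5 to 2.87 ± 0.249 CPM. The largest rises were those of TCF7L1, ADAMTSL4, NPR3, MROH2A, HIST1H2BE, MYH15, EFCAB8 and HIST1H1E, from 3.61 to 3.74. Without untreated replicate 1 they were between 2.65 and 2.84, and without untreated replicate 2 the lowest was 6.37. TCF7L1, a transcription factor of the Wnt pathway, was at 22.6 and 22.1 CPM in the treated libraries, at 0.269 CPM in untreated replicate 1 and at 3.11 CPM in untreated replicate 2. Without GNE987 replicate 1 these 8 rises were between 3.50 and 3.72, and without GNE987 replicate 2 between 3.68 and 3.86. They did not pass the threshold in either setting, where the spread came from the untreated pair alone, while the largest falls passed.

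Library size alone in place of TMM moved the median log2 fold change of all genes by -0.37 and gave 4103 higher and 7164 lower genes, a higher share of 36.4% against 48.0%, and no spike-in fixes the absolute level. The count of changed genes was 6070 without GNE987 replicate 1, 6215 without GNE987 replicate 2 and 12921 without untreated replicate 2, and that of genes changed at least 2-fold was 5509, 5607 and 9472.

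**Figure D2:**
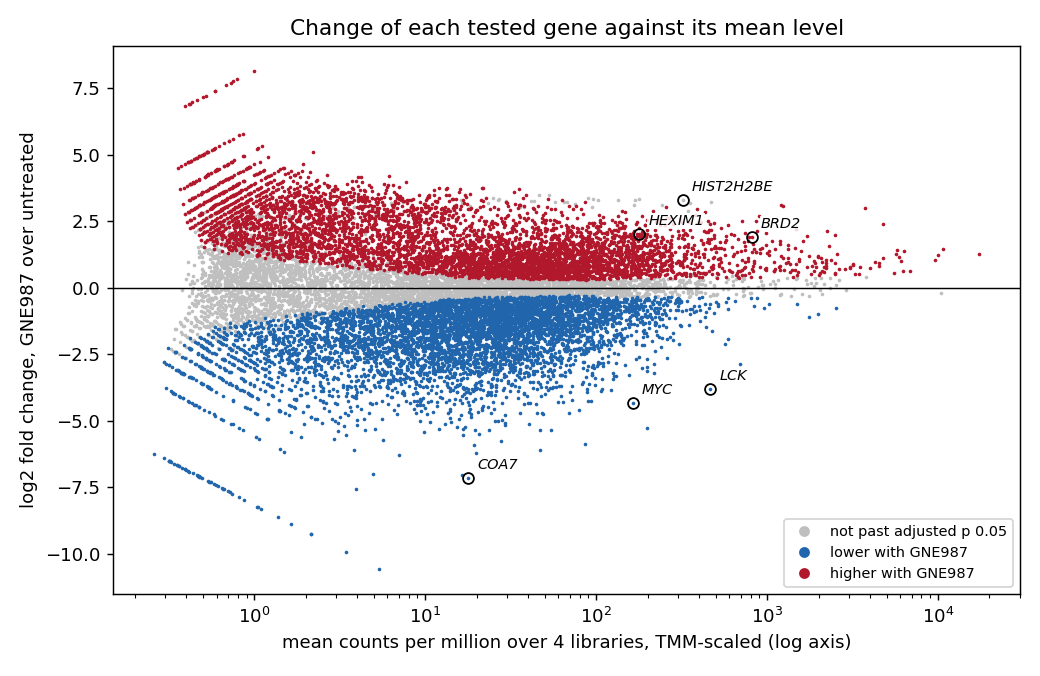
Log2 fold change of each of 15910 tested genes, GNE987 over untreated (vertical), against the mean TMM-scaled CPM over 4 libraries (horizontal, log axis); red and blue points passed an adjusted p of 0.05 and grey points did not. Falls reach further than rises among genes above 10 CPM, with COA7 at -7.16 and the largest called rise at 3.74.

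T-cell genes fell as a group. Of 40 tested genes of T-cell receptor signalling and the T-cell surface 31 fell and 4 rose, with a median log2 fold change of -2.01 (camera adjusted p = 1.22e-06, and adjusted p = 0.557 with an estimated correlation). CD1D, a lipid antigen-presenting molecule, was at -5.48 ± 0.21, the adaptor GRAP2 at -5.13 ± 0.25 and the costimulatory receptor CD28 at -2.73 ± 0.16. Transcription factors of the T-ALL core circuit fell in 14 of 19 cases and rose in 3 (median -1.77, camera adjusted p = 0.00236, and adjusted p = 0.557 with an estimated correlation). LYL1 was at -5.54 ± 0.21, MYB at -3.03 ± 0.16, IKZF1 at -2.85 ± 0.17 and TCF7 at -2.15 ± 0.13. Of 18 genes of the NOTCH pathway 10 fell and 4 rose (median -0.98, camera adjusted p = 0.231); DTX1 was at -2.69 ± 0.15 and RBPJ, the DNA-binding partner of NOTCH, at -1.88 ± 0.15.

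Growth genes fell as well. Of 42 MYC and ribosome biogenesis genes 32 fell and 2 rose (median -0.82, camera adjusted p = 6.2e-06, and adjusted p = 0.557 with an estimated correlation), with CDK4 at -3.85 ± 0.16, WDR43 at -4.72 ± 0.17 and PES1 at -3.31 ± 0.16. Nuclear genes of oxidative phosphorylation fell in 21 of 40 cases and rose in 5 (median -0.56, camera adjusted p = 0.0291, and adjusted p = 0.557 with an estimated correlation), such as NDUFS3 at -2.30 ± 0.15 and SDHD at -2.97 ± 0.20. The 13 mitochondrially encoded mRNAs, in contrast, rose in 13 of 13 cases (median 1.18, camera adjusted p = 0.00296, and adjusted p = 0.557 with an estimated correlation). They took 7.02% and 7.48% of the counts in the treated libraries, 3.72% in untreated replicate 1 and 4.73% in untreated replicate 2. Messages of cytosolic ribosomal proteins rose in 33 of 49 cases and fell in 1 (median 0.64, camera adjusted p = 0.00236, and adjusted p = 0.557 with an estimated correlation). With library size alone 22 of them were higher and 6 lower.

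Genes of DNA replication and of mitosis went in opposite directions. Of 46 replication genes 24 fell and 8 rose (median -0.49, camera adjusted p = 0.0433, and adjusted p = 0.557 with an estimated correlation). RFC2 was at -3.44 ± 0.17, CDC45 at -2.30 ± 0.13 and the helicase subunit MCM3 at -2.66 ± 0.16. Without GNE987 replicate 2 this list did not pass (adjusted p = 0.0516). Of 40 mitotic genes 30 rose and 4 fell (median 1.19, camera adjusted p = 0.000135, and adjusted p = 0.557 with an estimated correlation). CENPF, a kinetochore protein, rose by 1.83 ± 0.21, ANLN by 1.21 ± 0.14 and the motor KIF4A by 1.19 ± 0.14, and NDC80, also of the kinetochore, fell by 2.15 ± 0.15. Of 18 CDK inhibitors and G1 regulators 10 rose and 6 fell (median 1.51, mean 0.58, camera adjusted p = 0.413), with GADD45A at 1.38 ± 0.19 and RBL2 at -1.79 ± 0.15.

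Histone genes had the highest median of the lists. Of 20 tested genes 11 rose and 1 fell (median 3.10, camera adjusted p = 0.00329, and adjusted p = 0.557 with an estimated correlation), and without untreated replicate 2 the numbers were 19 and 1 with a median of 7.17. H3F3B, which encodes the replacement histone H3.3, rose from 699.8 ± 315 to 2709 ± 13.6 CPM, a log2 fold change of 1.95 ± 0.33, and of 2.56 without untreated replicate 2. HIST2H2BE had 582.5 ± 3.95 CPM with GNE987, 0.449 CPM in untreated replicate 1 and 118 CPM in untreated replicate 2 (adjusted p = 0.146). HIST2H2BE was singled out after its values were seen. Counts of single histone genes are uncertain, since near-identical copies share reads. The libraries were made from polyadenylated RNA, so these values cover only histone transcripts with a poly(A) tail, not all histone messages.

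Stress genes rose. Heat shock and immediate early genes rose in 16 of 20 cases and fell in 2 (median 1.94, camera adjusted p = 0.00569, and adjusted p = 0.557 with an estimated correlation; median 2.78 without untreated replicate 2). JUN, an immediate early transcription factor, was at 2158 and 2185 CPM with GNE987, at 34.3 CPM in untreated replicate 1 and at 471 CPM in untreated replicate 2 (adjusted p = 0.0499, and 0.147 and 0.149 without either treated library). HSPA8, a constitutive chaperone, fell by 0.98 ± 0.15. Genes of the unfolded protein and ATF4 response rose in 16 of 26 cases and fell in 6 (median 0.75, camera adjusted p = 0.0483, and adjusted p = 0.557 with an estimated correlation). With library size alone this list did not pass (adjusted p = 0.0534). SLC7A11, the cystine transporter, rose by 2.62 ± 0.30 and TRIB3 fell by 1.27 ± 0.12. HIF targets rose in 15 of 26 cases and fell in 2 (median 0.73, camera adjusted p = 0.0186, and adjusted p = 0.557 with an estimated correlation), among them P4HA1 by 1.45 ± 0.14. Autophagy and lysosome genes rose in 24 of 38 cases and fell in 8 (median 0.47, camera adjusted p = 0.0188, and adjusted p = 0.557 with an estimated correlation), with NPC1 at 1.19 ± 0.15 and ATG7 at -1.49 ± 0.21. With library size alone the autophagy list had 16 genes higher and 10 lower (median 0.10), the HIF list 11 and 5 (median 0.36) and the unfolded protein list 14 and 8 (median 0.38). Without the filter on low counts these 2 lists of the stress group, autophagy and unfolded protein, did not pass (adjusted p = 0.0603 and 0.109).

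Other pathways moved in both directions. Among 10 anti-apoptotic genes 4 rose and 2 fell (camera adjusted p = 0.423), with MCL1 at 1.92 ± 0.32 (2.53 without untreated replicate 2) and BCL2L1 at -1.71 ± 0.14; their median was 0.24, and -0.14 with library size alone. Among 21 pro-apoptotic genes 12 rose and 6 fell (median 0.70, mean 0.03, camera adjusted p = 0.536), or 8 and 7 with library size alone (median 0.33), with BAX at -1.70 ± 0.12 and the death ligand TNFSF10 at -4.11 ± 0.17. The list named for the cullin-RING VHL ligase, the enzyme that GNE987 recruits, also held genes that neddylate or exchange cullins in general. Of its 10 genes 6 were lower and 1 higher (median -0.91, camera adjusted p = 0.0641). NAE1, of the neddylation enzyme, was at -3.10 ± 0.16 and the ligase subunit CUL2 at -1.71 ± 0.17. Of 30 genes of cholesterol and fatty acid synthesis 16 rose and 6 fell (median 0.41, camera adjusted p = 0.0641), with MSMO1 at 1.45 ± 0.18 and FADS1 at -1.53 ± 0.13; with library size alone 13 rose and 9 fell (median 0.04). With the replicate number as a block these lists passed, at camera adjusted p = 0.0248 for the ligase and 0.0452 for the lipid genes. The ligase list, but not the lipid list, passed with library size alone (0.0357) and without the filter on low counts (0.00942). Neither passed with an estimated correlation (adjusted p = 0.557). Without untreated replicate 2 the medians were -0.92 for the ligase and 0.53 for the lipid genes. Of 29 interferon response genes 11 rose and 12 fell (camera adjusted p = 0.594), with IRF1 at -2.05 ± 0.13 and PSMB9 at -2.51 ± 0.16; their median of -0.01 was 0.08 with RLE factors, 0.18 with upper-quartile scaling and 0.25 without untreated replicate 2.

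Markers of other cell types changed in both directions. Of 8 tested myeloid markers 3 rose and 0 fell (median 2.74, camera adjusted p = 0.231). Their median was 3.56 without untreated replicate 2, and with library size alone 4 of them rose and 1 fell. CD14 was at 24.0 and 26.5 CPM with GNE987, at 0.135 CPM in untreated replicate 1 and at 4.49 CPM in untreated replicate 2 (adjusted p = 0.0272). CD14 did not pass with DESeq2 (adjusted p = 0.0679), with robust estimation (0.123), without GNE987 replicate 1 (0.126) or without GNE987 replicate 2 (0.139). MPO, the granulocyte peroxidase, was at 72.6 and 77.3 CPM with GNE987, at 0.0898 CPM in untreated replicate 1 and at 15.5 CPM in untreated replicate 2 (adjusted p = 0.0702). Among B-cell markers CD79A rose by 1.15 ± 0.15 and BLK fell by 2.84 ± 0.23 (camera adjusted p = 0.678). Erythroid and megakaryocyte markers rose in 2 of 3 cases (camera adjusted p = 0.149), with ITGA2B at 3.53 ± 0.38, and neural markers in 3 of 6 (camera adjusted p = 0.168); with library size alone 1 and 2 of them rose. The tested epithelial marker, ESRP1, fell by 2.78 ± 0.32 (camera adjusted p = 0.244). Fibroblast markers rose in 1 of 3 cases, COL1A1 by 2.49 ± 0.32 (camera adjusted p = 0.4), and their median of 0.35 was -0.02 with library size alone.

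By camera 13 of 28 lists passed, 5 lower and 8 higher, and 0 passed with an estimated correlation (0 at an unadjusted p below 0.05), while fry called 13 that were partly other lists. It lost 6 of the 8 rising lists, namely histone, heat shock, unfolded protein, HIF, autophagy and mitochondrial mRNAs (adjusted p from 0.0595 to 0.0842). It gained 6, namely NOTCH, the VHL ligase, interferon response and the erythroid, epithelial and fibroblast markers. Without untreated replicate 2 the medians of the rising lists were 1.39 for mitosis, 1.47 for mitochondrial mRNAs, 0.76 for ribosomal proteins, 0.92 for the unfolded protein list, 0.90 for HIF targets and 0.65 for autophagy. Those of the falling lists were -2.13 for T-cell genes, -1.81 for T-ALL factors, -0.84 for MYC and ribosome biogenesis, -0.52 for replication and -0.53 for oxidative phosphorylation. Adjusted over the list alone, the number of called members was equal to that over all genes in 25 of 28 lists. It was 17 in place of 16 for the G1 regulators, 23 in place of 22 for the unfolded protein list and 3 in place of 1 for the fibroblast markers, adjusted over the list alone.

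**Figure D3:**
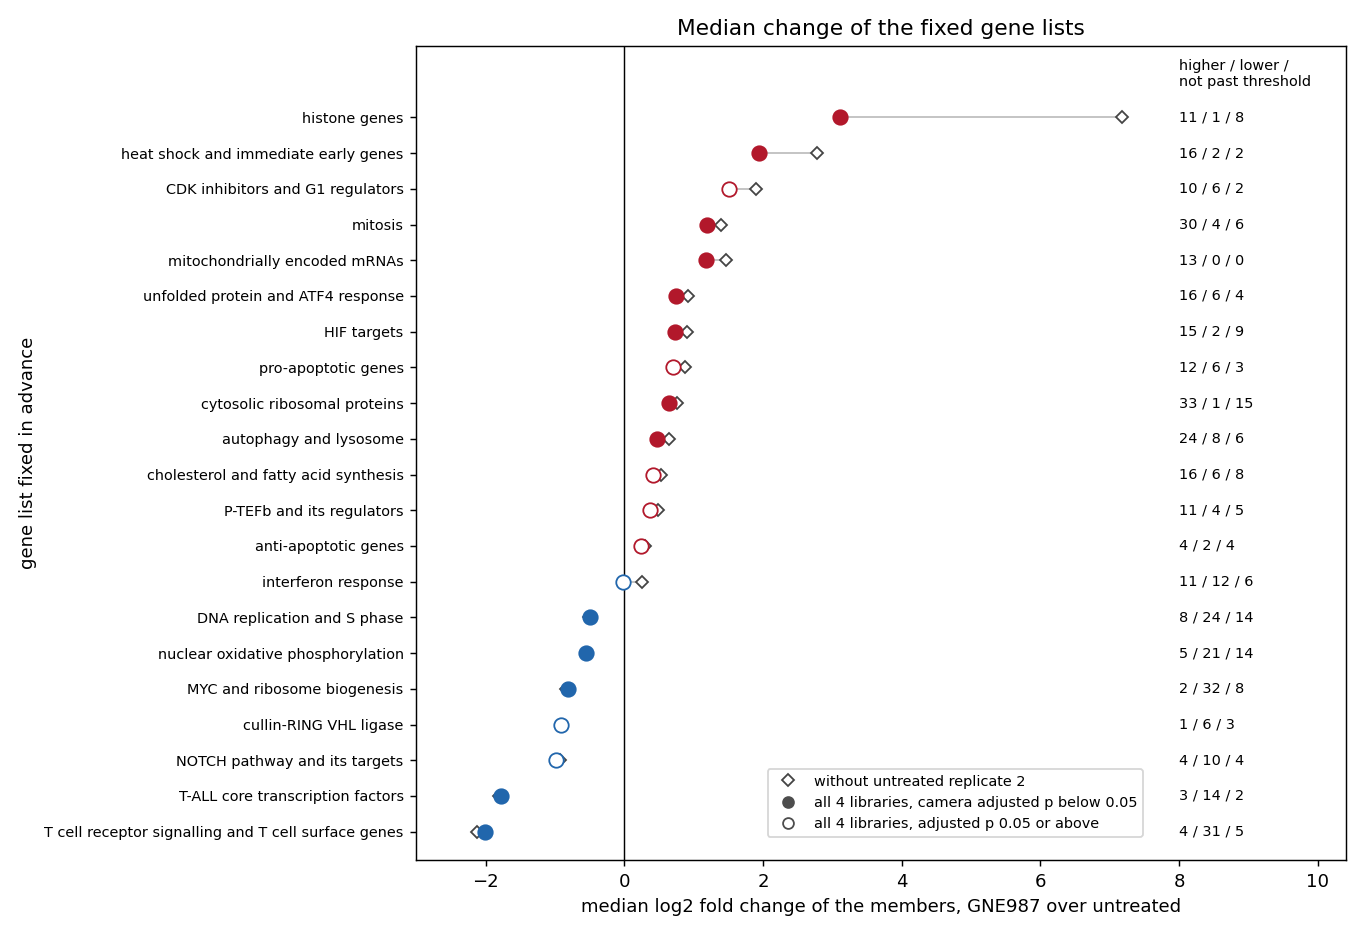
Median log2 fold change, GNE987 over untreated (horizontal), of the fixed gene lists except the BET family and markers of other cell types (vertical), with all 4 libraries (circles, filled where the camera adjusted p was below 0.05) and without untreated replicate 2 (diamonds); the numbers at the right count members higher, lower and not past the threshold. T-cell receptor genes have the lowest median at -2.01, and the histone median is 3.10 with all libraries and 7.17 without untreated replicate 2.

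Untreated replicate 2 was placed on the way from untreated replicate 1 (0%) to the mean of the treated libraries (100%) for gene classes chosen without it. The median position was 23.7% for 48 genes under 0.2 CPM in untreated replicate 1, 25.0% for 272 genes that were at least 4-fold higher, 25.7% for 293 genes above 100 CPM and at least 1.5-fold higher, and 25.9% for 825 genes at least 8-fold lower with GNE987. Of the 11387 changed genes 10390, or 91.2%, were displaced toward the treated libraries in untreated replicate 2. Untreated replicate 1 enters both sides of this comparison, and the genes were called with untreated replicate 2. The share is therefore not a test of displacement.

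**Figure D4:**
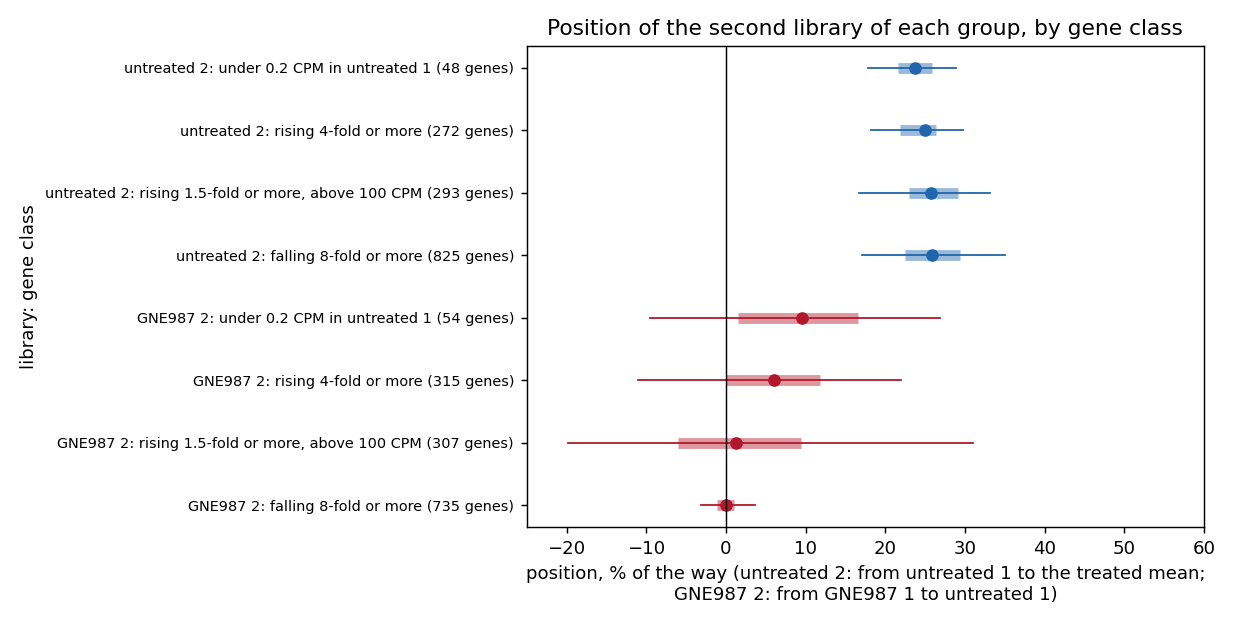
Position of the second library of each group (horizontal, percent of the way) by gene class (vertical); points are medians over genes, thick bars the quartiles and thin lines the 5th to 95th percentile. Untreated replicate 2 has medians from 23.7% to 25.9% in 4 gene classes, and GNE987 replicate 2 has medians from -0.03% to 9.51% of the way to untreated replicate 1.

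Per the authors' deposited table, an adjusted p below 0.05 was listed for 9977 genes, 4740 higher and 5237 lower. Of the 9824 of these that were tested here 9799 were also called here with the same sign. The authors' deposited table did not call 1588 of the genes called here. Of the largest rises TCF7L1, MROH2A, MYH15 and HIST1H1E were below 0.05 there, and ADAMTSL4, NPR3, HIST1H2BE and EFCAB8 were not.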

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

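All alternatives here were fixed before the data were examined. The count of changed genes, 11387, ranged from 6070 to 12921 when each library was left out in turn. The count changed at least 2-fold, 8303, ranged from 5509 to 9472 in the same way, and was 4890 with a filter of 10 CPM in 2 libraries, where only 9563 genes were tested. The other scalings, filters and tools gave 7737 to 11447 changed genes. The correlation of the deviations of same-numbered libraries was -0.00138 over genes, so no pairing by replicate number was seen. The larger difference within the untreated pair could hide one, so pairing is not excluded. With the replicate number as a block 9801 genes changed. Of 28 lists 13 passed, 12 to 16 with each library left out, 15 with the replicate block, and 0 with an estimated correlation; the cause was not tested.

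No direction of a called named gene or list turned under the alternatives run. Of 117 named genes 10 lost their call with robust estimation, 6 with DESeq2, 4 with library size alone, 19 without GNE987 replicate 1 and 20 without GNE987 replicate 2. The 8 largest rises were among those lost with robust estimation (adjusted p from 0.0536 to 0.17), and 4 of 8 passed with DESeq2. By fry 13 lists moved one way on balance and 26 changed in either direction. In the simulation with 200 changed genes 22% of 2-fold changes were recovered. The adjusted threshold is stricter there than with the many calls made here. Recovery by fold was not measured with many changed genes, so genes not called are not shown to be unchanged.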

Other observations

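The gene families below, and the tests on untreated replicate 2, were chosen after the data were seen. The tests on genes near zero were written before their results, with 2 exceptions. The comparison with evenly spread genomic DNA was written after, and that of divergent starts was not among those written beforehand.

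Genes for building mitochondria fell together. Of 77 mitochondrial ribosomal protein genes 63 fell and 6 rose (median -1.88; Fisher's exact test for lower calls against all other tested genes, adjusted p = 3.74e-15 over 14 groups, genes not being independent). Of 23 TOMM and TIMM protein import genes 16 fell and 4 rose (median -1.91, adjusted p = 0.00276). Of 38 proteasome subunits 29 fell and 1 rose (median -1.30, adjusted p = 2.64e-06). Members of the METTL, TRMT and ALKBH families, many of which methylate or demethylate RNA, fell in 37 of 45 cases and rose in 3 (median -1.52, adjusted p = 1.46e-09). The GIMAP genes, lymphocyte GTPases, fell in 7 of 7 cases (median -3.23, adjusted p = 0.00153). These medians stayed negative with RLE factors, upper-quartile scaling and library size alone.

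Other groups rose. Polyadenylated transcripts of histone genes as a whole were higher in 39 of 61 cases (median 3.24, and 7.78 without untreated replicate 2). Collagen genes rose in 12 of 20 cases and fell in 2 (median 1.68, Fisher's exact test adjusted p = 0.0477 for higher calls). Without untreated replicate 2 the collagen median was 2.37. Among lincRNA genes 323 of 670 rose and 114 fell (median 1.34), and among antisense genes, which this kit cannot tell from their partners, 415 of 862 rose and 123 fell (median 1.31). These medians stayed positive under the scalings tried. Keratin genes did not pass (1 of 6 lower, adjusted p = 0.454), nor did HOX genes (10 of 21 lower, adjusted p = 0.43) or glycolysis genes (8 of 14 higher, adjusted p = 0.112).

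Untreated replicate 2 lay between untreated replicate 1 and the treated libraries, and a weaker response of its cells that differs from gene to gene is argued against in 1 set of genes: in 48 genes nearly absent from untreated replicate 1, the SD of the log share was 1.12 times what counting and the spread of the treated pair allow. A candidate explanation is material or reads of treated cells in this library: the median share ranged by 0.0215 over 4 gene classes, from 23.7% to 25.9%. The medians of 19 gene lists ran from 23.0% to 29.5%, a range of 6.56 percentage points against a median of 5.56 over 10000 permutations of the members (p = 0.26), so a difference between lists stays open. The treated pair showed no common share, with class medians from -0.03% to 9.51%, although a stricter reading, all of them under 5%, was not met. Whether cells, RNA or reads were mixed, or a part of the cells had met the compound, stays open, and no other biological explanation was tested.

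Rises ended at 3.74 on the log2 scale among called genes above 10 CPM, while falls reached -7.16. Among the 8783 genes above 10 CPM with at least 1 read in untreated replicate 1, 98 rose by over 5 on the log2 scale without untreated replicate 2, against 0 with it. Falls of over 5 among these genes numbered 27 without untreated replicate 2 and 25 with it. The 20 largest falls moved by a median of 0.0876. Leaving out an untreated library that lies nearer the treated ones raises the largest rises whatever the cause. These numbers therefore argue for no explanation.

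Of 12080 genes at or under 0.5 CPM in untreated replicate 1, 203 were at 5 CPM or more in both treated libraries, 134 of them protein coding and 27 histone genes. Genomic DNA or unspliced RNA was tested in 4157 single-exon and sense-intronic genes at or under 0.5 CPM in untreated replicate 1. Their median was 0.0935 CPM in the treated libraries (upper quartile 0.275 CPM) and 0.0528 CPM in untreated replicate 1. A rise of most of these genes to the bound of 0.5 CPM set beforehand was not seen. Both medians lay under the floor for a gene without reads, 0.158 to 0.187 CPM, so a smaller rise cannot be judged. Of these genes 65 were at 5 CPM or more in both treated libraries. Genomic DNA or unspliced RNA therefore stays open. Evenly spread genomic DNA was compared in the 203 rising genes with the CPM predicted from exonic length and the pooled counts of genes near zero. Their median was 15.1 times the predicted CPM. They were picked for 5 CPM or more, which raises this ratio, so no conclusion is drawn from it. Uneven reads in single genes were not tested. Transcription running past the ends of expressed neighbours may account for a part: 24 of 203 such genes, 11.8%, began within 10 kb past the 3' end of an expressed gene on the same strand, against 7.19% of 9230 genes that stayed low (odds ratio 1.73, Fisher's exact test p = 0.0192, two-sided; divergent starts within 10 kb gave an odds ratio of 1.66, so the excess was not specific to 3' ends). An action of GNE987 on these genes themselves stays open.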
